A study of Komagataella pastoris with 4 samples.

How the data were processed

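Total RNA from 4 Pichia pastoris strains grown for 14 h on methanol, 1 library per strain, was depleted of ribosomal RNA with a kit made for bacteria and turned into sequencing libraries, per the labels' protocols, which do not state strandedness. The submitters' processing notes name bcl2fastq 2.19.0.316, fastp 0.19.6, Bowtie2, featureCounts 1.6.4 and DESeq2, without saying what each was used for. The genome build and annotation were not given in the sources used here. The values deposited by the authors are raw read counts per feature, whole numbers with no normalization, in 1 table of 5427 rows with 4 sample columns, whose names tie each to 1 strain. Of the rows, 5253 were protein-coding, 161 were miscellaneous RNA and 13 of other kinds, and 4644 carried a description of the product. Names were taken from those descriptions, because 0 of the locus tags and 0 of the protein accessions matched the reference gene table at hand, which is of another strain. Rows are cited by the table's own row identifiers in place of its locus tags. No row was described as a ribosomal RNA: the pattern meant to find such rows matched 13 protein-coding genes, so the share of ribosomal RNA in the libraries could not be measured. The 783 rows without a description could not be searched this way.

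Rows with a mean of at least 20 counts over the 4 libraries were kept, which left 5420 and removed 7. Libraries were scaled by TMM factors from edgeR 4.0.16 in R 4.3.3, and the factors were 1.1 for the wild type, 0.862 for the Mxr1-labelled, 1.207 for the Gal83-deletion and 0.874 for the Gcn5-deletion library. For each gene and deletion strain the log2 ratio to the wild type was taken after adding 0.5 to each count. Its 95% interval came from the exact Clopper-Pearson interval of the share of the pair's counts that fell in the deletion library. Reads were not marked with molecular identifiers, as far as the labels say, so duplicate reads would count as separate and make the intervals too narrow. The intervals cover counting error only, because each strain had 1 library. With 1 library per group no test between strains was possible, no p-value was computed, and genes were described by size: at least 2-fold with an interval excluding equality. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

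The counts were deep. The totals ran from 30582006 to 48539082, no row was at 0 in any library, and the lowest count in a library was 2 or 3. Every gene that differed by at least 2-fold also had an interval excluding equality, so the size and not the depth set the calls, and differences between cultures are the error that was not measured. The calling steps were tested on simulated counts with counting noise only. In each comparison 200 of 5421 genes were changed by known factors, all beyond 2-fold. At this depth near-full recovery was thus built in, so the test checks the computation and not errors between cultures. All changed genes were recovered (100.0%) in the Mxr1-labelled, Gal83-deletion and Gcn5-deletion comparisons, with 0, 1 and 1 false calls, and the intervals held the true ratio for 95.8%, 95.0% and 95.0% of genes.

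Gene lists were fixed as 36 sets of symbols, locus tags and description patterns before the data were examined. The deposited rows held no matching symbols or tags, so the patterns decided. The 32 lists with at least 4 measured members were used, which gave 96 medians over the 3 comparisons. A list's median log2 ratio was placed among 10000 random lists of the same size, matched on mean expression in 10 bins, as a description of these libraries. The genes named were also chosen by a rule fixed then: the deleted genes, all methanol utilisation genes, the 10 highest and 10 lowest described genes per comparison, up to 4 members with the largest ratios per list discussed, and described genes standing apart in 1 library. Under that rule, 1 and 3 undescribed genes were passed over among the highest and lowest of the Mxr1-labelled library, 2 and 3 in the Gal83-deletion library, and 2 and 1 in the Gcn5-deletion library. A gene stood apart when 1 library differed by at least 2-fold from each of the other 3 and those lay within 1.5-fold of one another. Overlaps between comparisons were set beside the product of the list sizes over the number of genes, and beside 100 simulated sets of strains without differences.

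The alternatives tried were total counts, DESeq2 1.42.0 size factors, upper-quartile factors, leaving out the 20 highest rows before scaling, no filter, a filter at a mean of 100 counts, 5 added to each count, and a 4-fold rule. Added after the data were seen were an analysis of protein-coding rows that share no reads with a neighbour, a methanol list with catalase and S-(hydroxymethyl)glutathione dehydrogenase, and lists without members whose descriptions name another pathway. There were 114 rows of split features and 41 rows whose counts lay within 5% of a neighbour's in each library. Overlapping and antisense genes cannot be told apart without strand, and near-identical copies can share reads, so single rows of such families are uncertain.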

Results

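RNA was sequenced from 4 strains of the methylotrophic yeast Pichia pastoris, each grown for 14 h in minimal medium with methanol as the carbon source. The strains were the parent GS115, called the wild type here, and 3 strains derived from it, each described as lacking 1 regulator. Mxr1 is a zinc-finger transcription factor needed for expression of methanol genes, Gal83 is a beta-subunit of the Snf1 kinase complex, and Gcn5 is the catalytic histone acetyltransferase of the SAGA and ADA complexes. Each strain was represented by 1 library, so no difference has a replicate check, and each comparison is between libraries. The deposited table held raw counts for 5427 features, of which 5420 were compared. Total counts were 48539082 in the wild type, 34646983 in the Mxr1-labelled library, 30582006 in the Gal83-deletion library and 30741258 in the Gcn5-deletion library. The median feature had 2906, 1630, 2083 and 1446 counts in the same order.

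Ratios to the wild type are log2 ratios of counts scaled by the trimmed mean of M-values (TMM). Brackets hold the exact 95% counting interval, which covers counting error only and not variation between cultures. A gene was called higher or lower when it differed by at least 2-fold and its interval excluded equality. The median width of these intervals was 0.179, 0.167 and 0.184 log2 units for the Mxr1-labelled, Gal83-deletion and Gcn5-deletion libraries. Genes are identified by the description in the deposited table and the table's own row identifier, such as gene4497 for alcohol oxidase. The table held no coordinates.

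The deleted genes were read first. The row for the histone acetyltransferase acting on histones H2B and H3 (Gcn5, gene3103) had 2570 counts in the wild type, 1840 in the Mxr1-labelled library, 3060 in the Gal83-deletion library and 3 in the Gcn5-deletion library. Its log2 ratio in the Gcn5-deletion library was -8.53 [-11.03 to -7.20]. The row described as 1 of the possible beta-subunits of the Snf1 kinase complex (gene1360), taken as Gal83 by the rule fixed beforehand, had 5215, 3996, 8 and 2263 counts in the wild-type, Mxr1-labelled, Gal83-deletion and Gcn5-deletion libraries. Its log2 ratio in the Gal83-deletion library was -8.73 [-10.03 to -7.84]. A different row, described as glucose repression protein GAL83 (gene161), had 13620 counts in the wild type and 5513 in the Gal83-deletion library, a log2 ratio of -0.77 [-0.82 to -0.73]. No row was described as Mxr1, so the label of the Mxr1 deletion was not checked. A row with the description of a carbon source-responsive zinc-finger transcription factor (gene4868), chosen after its values were seen, had 9114 counts in the wild type and 11606 in the Mxr1-labelled library, a log2 ratio of 1.19 [1.15 to 1.23], and was at log2 1.16 in the Gal83-deletion library. Whether gene4868 is Mxr1 was not settled. If it is, its counts go against a deletion of the whole row in the Mxr1-labelled library. As the label of this library was not checked, it is called Mxr1-labelled throughout, and every direction drawn from it rests on its label.

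The 5 listed methanol utilisation genes had lower levels than the wild type in all 3 deletion libraries. The factor was smallest in the Gcn5-deletion library for all 5 genes, and largest in the Mxr1-labelled library for 4 of them. Alcohol oxidase, which oxidises methanol to formaldehyde, had 1336239 counts in the wild type for its more abundant row (gene4497). That row was 97.1-fold lower in the Mxr1-labelled library, 11.2-fold lower in the Gal83-deletion library and 3.7-fold lower in the Gcn5-deletion library. The less abundant alcohol oxidase row (gene5263) was 5.78-fold, 6.57-fold and 3.46-fold lower. Dihydroxyacetone synthase, which fixes formaldehyde, was 8.85-fold, 3.58-fold and 1.96-fold lower in the same order for gene3440 and 5.32-fold, 4.85-fold and 2.41-fold lower for gene3442. Dihydroxyacetone kinase (gene3432) was 4.51-fold, 3.31-fold and 1.81-fold lower.

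All 5 methanol genes passed the size rule in the Mxr1-labelled and the Gal83-deletion libraries, and 3 of 5 did in the Gcn5-deletion library. The median log2 ratio of the list was -2.53, -2.28 and -1.27, at percentiles 0.1, 0.0 and 0.3 of 10000 random lists matched on mean expression. The list as fixed also named catalase, formaldehyde dehydrogenase, formate dehydrogenase and S-formylglutathione hydrolase. Its patterns matched no measured row of these, so the 5 genes are oxidase, synthase and kinase rows only. Peroxisomal catalase (gene1803) and a row described as S-(hydroxymethyl)glutathione dehydrogenase (gene3220), enzymes that remove hydrogen peroxide and formaldehyde, were added after the data were seen. Catalase had log2 ratios of -2.33, -0.25 and 0.41, and the dehydrogenase row had -0.36, -1.36 and -0.38. The 2 alcohol oxidase rows and the 2 dihydroxyacetone synthase rows carry near-identical descriptions, and the counting could have split reads between them, so the values of single rows are uncertain.

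**Figure D1:**
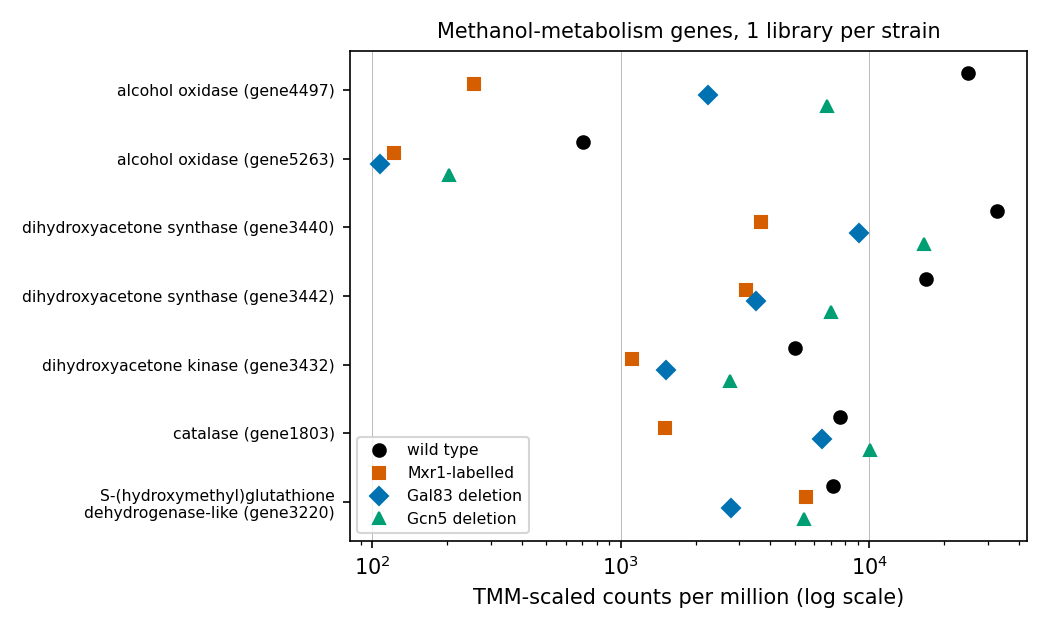
TMM-scaled CPM (log axis) of 7 genes of methanol metabolism, 1 point per library, with no error bars because each strain had 1 library. The wild type lies above all 3 deletion libraries for the 5 oxidase, synthase and kinase rows, while catalase is 5.04-fold lower in the Mxr1-labelled library and 1.33-fold higher in the Gcn5-deletion library.

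The series was designed to find genes that depend on Gcn5. Of the 10 highest described genes in the Gcn5-deletion library, 5 had descriptions of adhesins or other cell surface proteins. A lectin-like protein similar to the flocculin Flo1 (gene1454) was 47.3-fold higher [log2 5.51 to 5.61], from 3344 to 79503 counts. Of the rows with a GLEYA adhesin domain, gene1655 was 29.2-fold higher and gene4346 was at log2 4.39, a row described as zonadhesin (gene4334) was 18.5-fold higher and cell surface glycoprotein 1 (gene1948) was 9.81-fold higher. gene1655 and gene4334 went the other way in the other libraries, at log2 -4.78 and -4.84 in the Mxr1-labelled and -3.74 and -3.12 in the Gal83-deletion library.

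Other genes high in the Gcn5-deletion library were the row described as the silenced copy of ALPHA2 at HML (gene4439), which was 23.0-fold higher at low counts, from 57 to 664 [log2 4.14 to 4.95]. Inositol 1-phosphate synthase (gene1782) was 18.1-fold higher, the row named absent in melanoma 1 protein (gene5227) 13.4-fold, a high-affinity glucose transporter (gene1436) 12.1-fold and heat shock protein 9/12 (gene4715) 7.19-fold. Among 5420 genes, 220 were higher and 273 lower than in the wild type, 4.1% and 5.0%. Beyond 10-fold there were 9 higher and 2 lower genes.

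The lowest described gene after Gcn5 itself was a row with a glutathione S-transferase-like C-terminal domain (gene3172), 22.3-fold lower [log2 -4.52 to -4.44], which was also 19.7-fold lower in the Mxr1-labelled library. An aspartate aminotransferase-like protein (gene5269) was 7.55-fold lower, although it was 9.92-fold higher in the Mxr1-labelled and 3.07-fold higher in the Gal83-deletion library. The riboflavin synthesis enzyme 3,4-dihydroxy-2-butanone 4-phosphate synthase (gene4182) was 7.18-fold lower, a protein of Vid vesicles, which carry proteins to the vacuole (gene5373), 7.14-fold and a stationary phase-induced SOR/SNZ family protein (gene1241) 6.54-fold. The remaining 4 were a row described as RNA polymerase II subunit RPB1 (gene460, 6.36-fold), a MAPK-interacting-like protein (gene541, 6.28-fold), farnesyl pyrophosphate synthase (gene1155, 6.07-fold), and a cytokine inducing glycoprotein (gene4397, 6.06-fold). Several were not particular to this library: gene460 and gene1155 were 5.55-fold and 8.06-fold lower in the Mxr1-labelled and 3.54-fold and 4.22-fold lower in the Gal83-deletion library. In the Gal83-deletion library gene541 and gene1241 were also lower, by 3.27-fold and 4.27-fold.

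**Figure D2:**
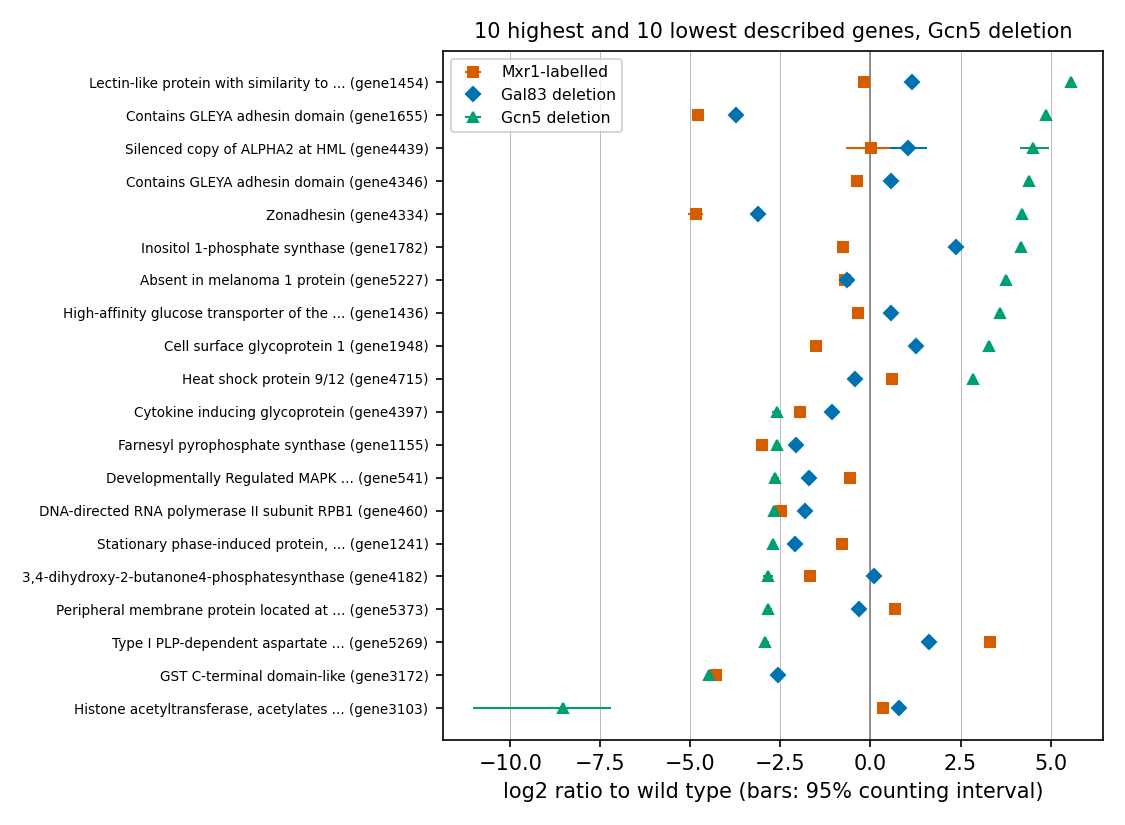
Log2 ratios to the wild type in the 3 deletion libraries for the 10 highest and 10 lowest described genes of the Gcn5-deletion library, with 95% counting intervals as bars where they exceed the marker. The lectin-like row gene1454 lies at 5.56 in the Gcn5-deletion library, against -0.18 in the Mxr1-labelled and 1.16 in the Gal83-deletion library.

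Part of the peroxisomal genes were lower in the Gcn5-deletion library. Of 33 listed genes, 13 were lower and 0 higher, with a median log2 ratio of -0.58 (percentile 0.0 of matched random lists). Peroxisomal membrane protein 11A (gene2507) was 5.16-fold lower, inheritance of peroxisomes protein 1 (gene4984) 4.42-fold, the receptor for peroxisomal targeting signal 1 (gene1871) 3.79-fold and biogenesis factor 2 (gene4324) 3.26-fold. Peroxisomal membrane protein PEX17 (gene4720) was 2.04-fold lower and stood apart in this library, at log2 0.42 and 0.22 in the Mxr1-labelled and Gal83-deletion libraries. By contrast, gene2507 and gene1871 were also lower in the Mxr1-labelled library, by 9.28-fold and 3.55-fold. Both were lower in the Gal83-deletion library too, by 2.36-fold and 2.03-fold, where 7 of the 33 genes were lower and 2 higher (median log2 -0.18, percentile 15.2).

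Of 9 measured members of the SAGA and ADA complexes, 2 were lower and 0 higher (median log2 -0.32, percentile 4.0). They were a SAGA subunit absent from the SAGA-like complex (gene1213, log2 -1.54) and SAGA associated factor 29 (gene804, log2 -1.02). The first was not particular to this library: gene1213 was also called lower in the Gal83-deletion library (log2 -1.34) and was at -0.58 in the Mxr1-labelled library. In the Mxr1-labelled and Gal83-deletion libraries gene804 was at log2 -0.68 and -0.22. The coactivator HFI1/ADA1 (gene1593), which holds SAGA together and lay outside the list, was 2.3-fold lower and stood apart in the Gcn5-deletion library. Of 44 other histone acetyltransferase, deacetylase and remodeler rows, which included Gcn5 itself, 3 were lower and 0 higher. Besides Gcn5 these were the NuA3 catalytic subunit (gene1904, log2 -1.26) and a SWI/SNF family ATPase (gene4111, log2 -1.13).

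Genes described as alcohol and aldehyde dehydrogenases and sugar transporters were among those higher in the Gcn5-deletion library. Of the 22 rows of the ethanol and acetate list, 6 were higher and 0 lower (median log2 0.36, percentile 97.2). Its patterns did not match the acetyl-CoA synthetase rows gene3907 and gene2210, which were at log2 1.40 and 0.95 in this library. The list took in 5 rows with descriptions of other pathways, and without them 6 of 17 were higher (median log2 0.60, percentile 99.9). Among the 6 were an alcohol dehydrogenase-like row (gene2541, 4.57-fold), a pyruvate decarboxylase (gene4154, log2 1.56) and aldehyde dehydrogenase rows gene3263 and gene881 (log2 1.54 and 1.32). In the Mxr1-labelled library gene2541 was also higher, by 4.9-fold, and gene3263 by 71.2-fold, while gene881 was at log2 -0.65. Of 17 rows of the sugar and glycerol list 4 were higher in the Gcn5-deletion library, including a hexose transporter (gene1, 3.04-fold), and 1 was lower, the glycerol proton symporter (gene4776, log2 -1.28). Of 27 chaperones 3 were higher and 0 lower (median log2 0.38, percentile 99.4), namely heat shock protein 9/12, an Hsp90-binding co-chaperone (gene855, log2 1.13) and an Hsp40 co-chaperone (gene1830, log2 1.10). The Hsp70 row Ssa3p (gene4104), chosen after its values were seen because it held the most counts of any row in this library, had 851808 counts in the wild type and 1221015 in the Gcn5-deletion library (log2 1.51).

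Genes of nitrogen uptake went both ways. Of 41 listed genes 7 were lower and 3 higher, with the ammonium transporter MEP2 (gene1243) at log2 -1.97, the general amino acid permease (gene336) at -1.74 and the permease AGP1 (gene2343) at 1.35. Of 13 rows of the amino acid biosynthesis list 3 were lower, which were sulfite reductase (gene3151, log2 -1.79), ATP phosphoribosyl transferase of histidine synthesis (gene1068, log2 -1.25) and methionine synthase (gene2890, log2 -1.06). In the Mxr1-labelled and Gal83-deletion libraries gene2890 was at log2 -2.39 and -2.39, gene3151 at -1.47 and -0.92, and gene1068 at 0.02 and 0.64. Of 40 cell wall genes 6 were higher and 4 lower in the Gcn5-deletion library. Beta-1,3-glucanosyltransferase rows gene239 and gene238, neighbours with matching descriptions, were at log2 1.99 and 1.96, and a protein that joins chitin to glucan (gene628) was at -1.51.

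In all, 22 genes stood apart as higher and 12 as lower in the Gcn5-deletion library, meaning that this library differed by at least 2-fold from each of the other 3, which lay within 1.5-fold of one another. With total counts they were 9 and 29. The higher ones included a protein kinase-like row (gene35, 4.21-fold), uricase (gene1975, 4.18-fold), AP-3 complex subunit delta-1 (gene1437, 4.06-fold), a life-span regulatory factor (gene2675, 3.81-fold) and a row named Holo (gene203, 3.12-fold). The lower ones included a negative regulator of the RAS-cAMP pathway (gene4924, 3.06-fold), the plasma membrane arginine permease (gene1473, 2.8-fold) and an aspartate aminotransferase-like row (gene2303, 2.06-fold). The balance of calls depended on scaling: higher genes made up 44.6% of the calls with TMM and 15.9% with total counts, which moved the median of all genes from -0.01 to -0.34. Genes just past 2-fold are therefore less firm than those at the extremes.

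The Mxr1-labelled library was set against the wild type to show the genes that follow the loss of this regulator on methanol, as far as its label holds. The highest described genes included enzymes and carriers of acetate activation, carnitine transport and the glyoxylate cycle, which turn acetyl units into cell carbon. A membrane protein for ammonia export (gene483) was 124-fold higher [log2 6.91 to 6.98], from 7051 to 487254 counts. Carnitine acetyl-CoA transferase (gene4293) was 87.7-fold higher, the carnitine carrier Crc1 (gene2069) 73.2-fold, an aldehyde dehydrogenase (gene3263) 71.2-fold and acetyl-CoA synthetases gene3907 and gene2210 were 53.0-fold and 40.7-fold higher. Isocitrate lyase (gene1180) was 50.4-fold higher, malate synthase 2 (gene5220) 48.9-fold, an outer mitochondrial carnitine acetyltransferase (gene890) 48.0-fold and a row of the acid proteases (gene4025) 45.6-fold.

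The lowest genes in the Mxr1-labelled library after alcohol oxidase were a class II fructose-bisphosphate aldolase variant (gene655), 68.8-fold lower [log2 -6.19 to -6.02], and a papain-like cysteine protease row (gene5264), 65.3-fold lower. The zonadhesin row gene4334 and the GLEYA adhesin row gene1655 were 28.7-fold and 27.4-fold lower. A row named C-jun-amino-terminal kinase-interacting protein 3 (gene2467) was 20.8-fold lower, a venom allergen-like row (gene4283) was at log2 -4.32, the transferase-like row gene3172 and a peroxisomal nudix pyrophosphatase acting on coenzyme A (gene3725) were 19.7-fold lower each, and a lectin and glucanase-like row (gene4789) was 16.7-fold lower. Of 5420 genes, 432 were higher and 559 lower, 8.0% and 10.3%, with 27 and 28 beyond 10-fold.

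Of the 33 peroxisome genes 12 were lower and 1 higher in the Mxr1-labelled library (median log2 -0.50, percentile 0.0). Peroxisomal membrane associated protein 20 (gene1412) was 16.1-fold lower and membrane protein 11A (gene2507) 9.28-fold lower, and the 1 higher member was carnitine acetyl-CoA transferase. Of 8 fatty acid beta-oxidation genes 4 were higher and 2 lower (median log2 1.75, percentile 100), and the 4 were the 3 carnitine acetyltransferases, including gene3523 at log2 3.49, and the carrier Crc1, which move acetyl and acyl groups between compartments rather than oxidise fatty acids. Of the 20 rows of the tricarboxylic acid cycle list 8 were higher and 1 lower (median log2 0.61, percentile 99.5). The list took in 4 rows of lysine and leucine synthesis, of which homocitrate synthase (gene1275, log2 1.18) was higher, and without them 7 of 16 were higher and 1 lower. The higher rows included a malate dehydrogenase-like row (gene4503, log2 2.13), succinate dehydrogenase rows gene1346 and gene4600 (log2 2.04 and 1.55) and aconitase (gene108, log2 1.69). Of 5 glyoxylate cycle and gluconeogenesis genes, leaving out an isopropylmalate synthase that the list took in, 3 were higher, with pyruvate carboxylase (gene1676) at log2 1.26, and 1 was lower, malate synthase G (gene1316) at -1.48.

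Nitrogen genes split in the Mxr1-labelled library, with 7 of 41 higher and 9 lower. The urea transporter Dur3 (gene2970) was 13.6-fold lower and the ammonium transporters MEP2 (gene1243) and MEP3 (gene2102) 10.2-fold and 5.52-fold lower, while proline oxidase (gene284) was 13.5-fold higher. Autophagy genes, 5 of 12 higher and 0 lower, had a median log2 ratio of 0.73 (percentile 99.8), with Atg8 (gene4630) at 2.26 and the kinase Atg1 (gene2351) at 1.80. Of 40 cell wall genes 11 were lower and 4 higher (median log2 -0.29, percentile 0.5). Chaperones were lower in 5 of 27 cases and higher in 0 (median log2 -0.49, percentile 0.4), with the Hsp70 exchange factor Fes1 (gene3018) 6.6-fold lower.

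The genes that stood apart in the Mxr1-labelled library were 62 higher and 45 lower, and 28 and 68 with total counts. The mitochondrial succinate/fumarate transporter (gene4652) was 25.4-fold higher, a NAD(P)-linked oxidoreductase (gene4798) was 10.2-fold lower and an actin-like ATPase domain row (gene1425) 5.11-fold lower. Higher genes made up 43.6% of the calls with TMM, 33.6% with upper-quartile factors and 18.4% with total counts, which put the median of all genes at -0.01, -0.12 and -0.36. The 10 highest rows took 21.8% of all counts in this library and 16% in the wild type.

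In the Gal83-deletion library the cytosolic ribosomal protein genes were lower almost throughout. Of 78 genes, 69 were lower and 0 higher, with a median log2 ratio of -1.77, a 3.41-fold difference (percentile 0.0). Without rows MRP2 and MRP51, names of mitochondrial ribosomal proteins in baker's yeast, 69 of 76 were lower. The 40S protein S28 (gene4046) was 9.32-fold lower, the 60S protein nearly identical to Rpl9A (gene721) 6.1-fold, the acidic protein P0 (gene63) 5.61-fold and S22 (gene2531) 5.28-fold. The same list had 9 of 78 lower and 1 higher in the Mxr1-labelled library (median log2 -0.56) and 1 of 78 lower and 0 higher in the Gcn5-deletion library (median log2 -0.21), each also at percentile 0.0 and against the same wild-type library. Ribosome biogenesis genes lay closer to the wild type, with 3 of 56 lower, 2 higher and a median log2 ratio of -0.38 in the Gal83-deletion library, at percentile 0.0. In the Gcn5-deletion library 3 of these 56 were higher, and their median log2 ratio was 0.32 with TMM, at percentile 100, and -0.02 with total counts.

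The highest described genes of the Gal83-deletion library were a protein kinase-like row (gene3391), 41.3-fold higher [log2 5.29 to 5.45], and several redox proteins. A thioredoxin-like protein (gene999) was 21.5-fold higher, glutathione peroxidase (gene2096) 15.0-fold and NADPH oxidoreductases with a flavin cofactor (gene3935 and gene3937) 14.1-fold and 10.2-fold. A papain-like protease row (gene1618) was 18.8-fold higher, dehydrogenase-like rows with a NAD(P)-binding fold (gene3859 and gene2389) 15.0-fold and 13.6-fold, a septicolysin row (gene5378) 14.3-fold and a copper-exporting ATPase (gene4601) 12.6-fold. Of 36 genes of oxidative stress and thiol defence 7 were higher and 5 lower (median log2 0.32, percentile 98.6).

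The lowest after Gal83 itself were an actin patches distal protein (gene484), 27.9-fold lower [log2 -4.88 to -4.72], a low-affinity iron transporter (gene1662), 15.7-fold lower, the GLEYA adhesin row gene1655, 13.4-fold lower, alcohol oxidase, and a subtilisin-like protease (gene2877), 10.5-fold lower. S28 followed, then the papain-like row gene5264 (8.82-fold), the zonadhesin row gene4334 (8.71-fold), and a glycoside hydrolase (gene4699, 8.47-fold). Of 5420 genes 594 were higher and 579 lower, 11% and 10.7%, with 15 and 7 beyond 10-fold.

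Lists of energy metabolism went different ways in the Gal83-deletion library. Of 13 glycolysis genes 4 were higher and 1 lower (median log2 0.06), and of 20 tricarboxylic acid cycle rows 1 was higher and 4 lower (median log2 -0.45). The 1 higher row was homocitrate synthase (gene1275, log2 1.07). Without the 4 rows of lysine and leucine synthesis, 0 of 16 were higher and 4 lower (median log2 -0.55, percentile 2.4). Leaving out an enolase-phosphatase row, 4 of 12 glycolysis genes were higher and 1 lower (median log2 0.29, percentile 88.7). Of 47 oxidative phosphorylation genes 9 were lower and 3 higher (median log2 -0.52, percentile 0.0), with ATP synthase subunit g (gene3459) at -2.34 and complex I subunit rows gene447 and gene499 at -1.77 and -1.62. Phosphoenolpyruvate carboxykinase (gene1609), which starts glucose formation from oxaloacetate, was 7.28-fold lower, and glycerol kinase (gene4542) was 3.76-fold higher. Of 57 cell cycle and DNA replication genes 13 were lower and 5 higher (median log2 -0.21, percentile 1.7), with a G1 cyclin (gene868) 7.21-fold and the mitotic cyclin CYB1 (gene2954) 4.22-fold lower. The transcription factor of the unfolded protein response (gene720) was 6.74-fold higher.

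The Gal83-deletion library had the most genes standing apart, 122 higher and 87 lower, and 194 and 22 with total counts. They included the thioredoxin-like row gene999 and the dehydrogenase-like row gene3859 among the higher, and a serine/threonine kinase (gene4086, 7.82-fold) and the 60S protein L22-like 1 (gene5380, 4.13-fold) among the lower. Higher genes made up 50.6% of its calls with TMM and 61.1% with total counts, where the median of all genes was 0.14 in place of 0.01. With upper-quartile factors the balance went the other way, to 44.3% and a median of -0.06.

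**Figure D3:**
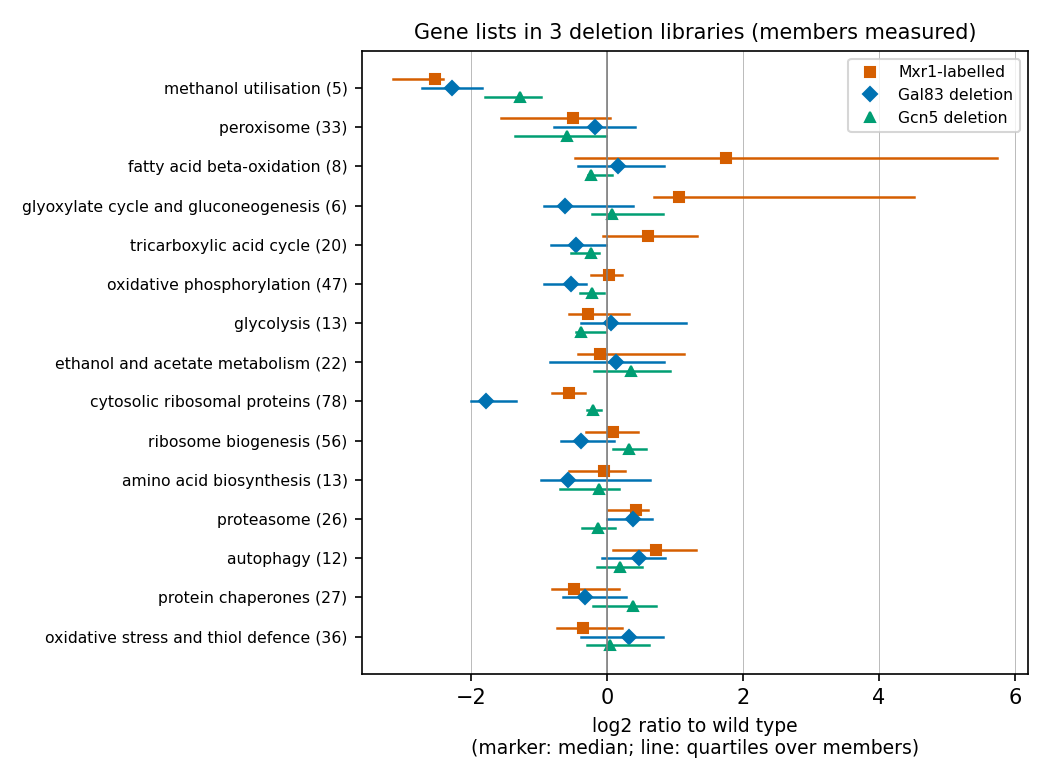
Median log2 ratio to the wild type (marker) and quartiles over members (line) of 15 gene lists as fixed beforehand in the 3 deletion libraries, with the number of measured members in brackets. The ethanol and acetate list does not hold the acetyl-CoA synthetase rows gene3907 and gene2210. The methanol list lies at -2.53, -2.28 and -1.27, and the cytosolic ribosomal proteins at -1.77 in the Gal83-deletion library against -0.56 and -0.21 in the Mxr1-labelled and Gcn5-deletion libraries.

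The calls of the 3 comparisons overlapped, more among lower than among higher genes. Lower in all 3 deletion libraries were 65 genes, against 3.0 for independent lists of these sizes, and higher in all 3 were 12, against 1.9. The 12 became 5 with total counts and 6 with upper-quartile factors. The genes lower in all 3 included the 2 alcohol oxidase rows, the aldolase variant gene655, farnesyl pyrophosphate synthase, and transaldolase rows gene2050 (5.81-fold, 5.01-fold and 4.84-fold in the Mxr1-labelled, Gal83-deletion and Gcn5-deletion libraries) and gene2049 (5.65-fold, 4.39-fold and 4.51-fold), enzymes of the pentose phosphate pathway. Their neighbour gene2048, a transaldolase row added after the data were seen, was at log2 -0.04, 0.97 and 0.25. By pairs, 202 genes were lower in both the Mxr1-labelled and Gal83-deletion libraries (59.7 for independent lists), 135 in the Mxr1-labelled and Gcn5-deletion libraries (28.2) and 85 in the Gal83-deletion and Gcn5-deletion libraries (29.2). The corresponding counts of higher genes were 107 (47.3), 56 (17.5) and 53 (24.1), and the counts of genes called in opposite directions were 67 (107.4), 50 (44.4) and 47 (53.4).

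All comparisons used the same wild-type library. Simulated strains with no difference from it, which held counting noise only, shared at most 1 called gene. At this depth that was close to fixed in advance. The simulation is no yardstick for a deviation of the wild-type culture, which it did not hold. Part of the overlap beyond independent lists may come from this 1 wild-type library, which could not be split. The covariance of log2 ratios across genes was 0.272, 0.18 and 0.113 for the 3 pairs in the order above, against 0.0015 from counting noise in the simulated strains. The correlations across genes, which are not independent replicates, were 0.33, 0.30 and 0.20, against 0.38, 0.35 and 0.37 in the simulated strains, where they arise from shared counting noise alone. The wild type itself stood apart in 19 genes, 15 where it was the higher and 4 where it was the lower. In the first set were the transaldolase rows gene2049 and gene2050, and in the second an iron-sulfur cluster scaffold protein (gene2905, log2 1.52, 2.01 and 1.78 in the deletion libraries) and a protein of transcription initiation at TATA promoters (gene1050, log2 1.37, 1.24 and 1.01). Between libraries, 493 genes differed by the size rule from the wild type to the Gcn5-deletion library, 991 to the Mxr1-labelled and 1173 to the Gal83-deletion library, and 1408, 960 and 1386 differed between the Mxr1-labelled and Gal83-deletion, Mxr1-labelled and Gcn5-deletion, and Gal83-deletion and Gcn5-deletion libraries.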

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

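The analysis of rows sharing no reads, the enlarged methanol list and the lists without members of other pathways were chosen after the data were seen. No paired analysis was possible because each group held 1 library and no result came from a test across replicates. Leaving out the 20 highest rows before scaling, dropping the filter, a filter at a mean of 100 counts, adding 5 to each count and using only protein-coding rows that share no reads each left all 21 counts and methanol medians within 1.5 times or within counting error. No gene call of the 3 comparisons changed direction under any of these or the settings below. Of 861 single-gene ratios and list medians, 819 moved beyond counting error with total counts and 1 more turned sign. With upper-quartile factors 432 moved, with DESeq2 size factors 22 and with rows that share no reads 2. Leaving out members of other pathways moved 11 list medians beyond counting error and left 13 within it.

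Of the scalings, total counts moved the most results, and the cause of each shift was not tested. With total counts, 231 genes were higher and 1023 lower in the Mxr1-labelled library, and 111 were higher and 588 lower in the Gcn5-deletion library. Genes higher in all 3 numbered 5, and 482 were lower in at least 2. Genes standing apart numbered 28 higher and 68 lower in the Mxr1-labelled, 194 and 22 in the Gal83-deletion and 9 and 29 in the Gcn5-deletion library, with 0 lower in the wild type. The methanol medians became -2.88, -2.14 and -1.6 in the Mxr1-labelled, Gal83-deletion and Gcn5-deletion libraries, and the ribosome biogenesis median in the Gcn5-deletion library turned to -0.02. Upper-quartile factors gave 6 genes higher in all 3, 2 standing apart lower in the wild type, and methanol medians of -2.65, -2.35 and -1.29. DESeq2 size factors moved the Gal83-deletion median to -2.3.

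By construction the 4-fold rule lowered the counts, to 91 higher and 134 lower in the Mxr1-labelled, 77 and 106 in the Gal83-deletion and 37 and 31 in the Gcn5-deletion library. Then 0 genes were higher and 7 lower in all 3, and 10 were higher and 47 lower in at least 2. The enlarged methanol list, with its less affected members, had medians of -2.41, -1.84 and -0.97. Depth was not the limit for named genes, apart from the deleted genes with 8 and 3 counts and the ALPHA2 row with 57 counts in the wild type. The missing replicates were.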

Other observations

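Histone genes did not move as a block. In the Mxr1-labelled and Gal83-deletion libraries 3 of 10 rows described as histones were higher and 2 lower. The neighbouring core histone rows gene1886 and gene1887 were at log2 -3.49 and -3.49 in the Mxr1-labelled library, -1.89 and -1.48 in the Gal83-deletion library and -1.31 and -1.38 in the Gcn5-deletion library. The neighbours gene1623 and gene1624 were at 1.54 and 1.79, 1.36 and 1.92, and 0.97 and 0.07 in the same order. A cyclin described as induced by Gcn4 (gene419) was 6.33-fold higher in the Mxr1-labelled and 5.12-fold higher in the Gal83-deletion library, but 4.12-fold lower in the Gcn5-deletion library. The row described as GAL83 (gene161) was 3.24-fold lower in the Gcn5-deletion, 2.06-fold in the Mxr1-labelled and 1.71-fold in the Gal83-deletion library. The other row, gene1360, taken as the deleted Gal83, was at log2 -0.21 in the Gcn5-deletion library.

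Iron and copper genes spread both ways without a shift of the list. Of 32, the Gal83-deletion library had 8 higher and 7 lower, the Mxr1-labelled library 6 and 4, and the Gcn5-deletion library 2 and 3, with medians of 0.01, -0.06 and -0.04. A siderophore ferric reductase (gene5165) was 13.2-fold lower in the Mxr1-labelled and 4.48-fold lower in the Gal83-deletion library, and the high-affinity iron permease (gene852) was 3.2-fold lower in the Gcn5-deletion library. Of 26 proteasome genes 1 or 0 passed the size rule in each library, although the list's median reached log2 0.43 and 0.38 in the Mxr1-labelled and Gal83-deletion libraries (percentiles 98.7 and 98.1).

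In the 3 patterns weighed next, the test of chromosome ends and its bound were set before its result was seen, and all other tests were chosen after. The value fell 0.2 percentile points short of that bound, which as written would count against position. The standard error from the number of random lists was 0.16, and the choice to leave position open within 2 standard errors was made after the value was seen. In each pattern strain and culture coincide, so a difference between single cultures in growth state or density stays open, untested, beside an effect of the deletion.

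The adhesin and flocculation rows of the Gcn5-deletion library, put together after such rows were seen among its highest genes, made the first pattern: 5 of 9 were higher and 0 lower, with a median log2 ratio of 1.58. The scalings tried put the median of all genes in this library between -0.01 and -0.34. That shift alone is too small to make the pattern, and the lowest of the 5, which were picked for passing 2-fold, stayed at log2 1.25. As several lie near chromosome ends, position was tested on the 155 rows among the outer 20 of each end, in the order of the table and by the chromosome in the locus tag, that carry no such description. Of these 16.1% were higher and 9.0% lower, against 4.1% and 5.0% of all genes (20.6% and 11% against 11% and 10.7% in the Gal83-deletion, and 13.5% and 20% against 8.0% and 10.3% in the Mxr1-labelled library), and their median of 0.09 lay at percentile 97.3, so position near an end cannot be told apart from other causes for the adhesin rows there, as the miss is within sampling error and the ends hold larger shares of both higher and lower rows in this library. Of the 5 adhesin or flocculation rows away from the ends, which position by this definition does not cover, 2 were higher and 0 lower (median log2 0.92). Of these 2, gene4334 lies shortly past the outer 20 rows, near the end row gene4346, so position may still bear on it. The other, gene1454, is the highest and lies farther in.

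The ribosomal protein genes of the Gal83-deletion library made the second pattern. The scalings tried put the median of all genes in this library between -0.06 and 0.14. That shift alone is too small to make the pattern, and the highest median of the list over the scalings was log2 -1.64. A drop of all genes for making ribosomes by a like amount is argued against. The lower quartile of the ribosome biogenesis list was -0.67, above the upper quartile of the ribosomal protein list at -1.33. The shift was not limited to ribosomal protein genes, since the ribosome biogenesis and oxidative phosphorylation lists had medians of -0.38 and -0.52, both at percentile 0.0. The ribosomal protein list also lay at percentile 0.0 in the other 2 deletion libraries, at -0.56 and -0.21, so part of the difference may come from the 1 wild-type library they share.

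The 10 highest described genes of the Mxr1-labelled library, most of them for acetyl-CoA, carnitine and glyoxylate enzymes or carriers, made the third pattern. The scalings tried put the median of all genes in this library between -0.01 and -0.36. That shift is too small to make ratios of this size, and the lowest of the 10, which were picked as the highest, stayed at log2 4.99. An exchange of labels with either of the other deletion libraries is argued against, because those 2 libraries held at most 0.27% of the wild-type level of their own deleted gene. An exchange with the wild type cannot be told apart from a correct label by a deleted gene, since no row was named Mxr1 and the zinc-finger row gene4868 was near 0 in neither library, at log2 1.19 in the Mxr1-labelled and also 1.16 in the Gal83-deletion library. The 97.1-fold lower alcohol oxidase row goes with a correct label, while the level of gene4868 goes against it if that row is Mxr1.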
